A study of Mus musculus with 19 samples.

How the data were processed

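The series holds 19 bulk MARS-seq libraries from mouse pancreas in 5 groups. Per the labels' protocols, exocrine cells of MIP-GFP mice were infected overnight with the adenovirus Ad-M3-mCherry or the control Ad-mCherry, plated on collagen after 24 h, and dissociated and sorted on day 6. Islets were cultured overnight and sorted for GFP 24 h after isolation. Libraries were made from mRNA caught on oligo(dT) beads and sequenced on a NextSeq 500. The description of GFP- replicate D says day 3, while its protocol and the column name of the deposited table say day 6, and the library was kept as day 6. Replicate letters C, D, E and F are those of the descriptions and column names; the controls hold C, E and F, although the series text states 4 biological replicates.

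The values used are raw counts per gene, as deposited, in 1 table of 15569 genes whose columns all mapped to a sample. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.8.3, STAR, HTSeq and DESeq2 were used with the mouse build mm10. The role of each tool, the gene annotation, whether unique molecular identifiers were collapsed and any gene filter are not given in the sources used here. No mitochondrially encoded gene was in the table. Deposited counts were whole numbers with totals that differ between libraries, so they were tested as counts.

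Everything else was computed from these counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered by edgeR's filterByExpr on the groups (min.count 10, min.total.count 15), which left 12442 genes. Library sizes were scaled by TMM, and 1 quasi-likelihood fit (robust glmQLFit, glmQLFTest) of all 19 libraries with group as the only factor served all 6 comparisons. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Standard errors come from the same fit. CPM are scaled by TMM, log2 CPM used a prior count of 2, and SD is over libraries. For genes with no count in a group the fold change is given as a bound, from a floor of 3 counts over the group, and for genes with 1 to 3 counts as a 95% counting interval. That interval covers sampling of counts only.

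Lists of genes were written from general knowledge before the data were examined. Of 20 lists, 18 had at least 5 measured members and were tested with camera (preset correlation 0.01), adjusted over the 108 tests of 18 lists in 6 comparisons. Delivered factors hold 3 genes and were reported by gene, and mitochondrially encoded genes had none measured. Beside camera were run camera with an estimated correlation, fry, and counts of members called over all genes and adjusted over the list alone. REST targets and granule genes share 11 members, endocrine transcription factors share 3 with the Notch list and 1 with REST targets, and the immediate early and p53 lists share Btg2. The position between control and islet cells used 5 lists and an exact permutation test of 4 against 4 libraries.

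Genes named in the text follow a rule fixed with the lists. Per comparison they are (1) the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 50 CPM in the higher group and no overlap of libraries, (2) Pdx1, Neurog3, Mafa, Ins1, Ins2, Gcg and Sst, and (3) up to 4 members with the smallest adjusted p of each list that passed or had at least 3 members called. Exceptions are marked where they occur.

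Before use the scripts were tested on simulated counts with 50 genes changed at each of 4 fold changes. For GFP+ against GFP- cells edgeR recovered 8, 52, 96 and 98% of genes changed 1.5, 2, 4 and 8-fold, with 6 false among 133 calls; for GFP- against control cells it recovered 12, 48, 94 and 100%, with 6 false among 133. In the simulation, changes of 1.5-fold were thus mostly missed. The real comparisons called far more genes, which eases the adjusted threshold, so these rates need not hold there. For GFP+ against GFP- cells 831 genes were called higher and 1337 lower, of which 258 and 865 reached 2-fold. DESeq2 made 12 false of 141 and 7 of 135 calls, and limma voom 3 of 129 and 8 of 131. Of 100 unchanged lists camera gave an unadjusted p under 0.05 for 1 and 0, and fry for 5 and 5. Those lists were random genes simulated independently, so they do not show how camera behaves when members are correlated. In the data the estimated correlation was 0.303 for fibroblast markers in GFP+ against GFP- cells. It was 0.602 for endothelial markers in double-negative against control cells.

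Alternatives were DESeq2, RLE factors, scaling without the 20 most abundant genes, no filter, only the 2 groups compared in the fit, the replicate letter as a block, limma voom with quality weights, thinning to the shallowest library, a 2-fold threshold, and leaving out each library in turn. Leaving out libraries for the list tests and the correlation across genes was added after the data were seen. RLE factors moved the median log2 fold change over all genes by -0.0831 at the largest, for GFP+ against control cells. Whether letters pair libraries was checked by correlating deviations from group means over 7650 genes. For GFP- against control cells every pair was above 0.1 (0.115 for C, 0.209 for E and 0.286 for F) and matched its own letter best. Between GFP+ and control cells the same letters gave 0.0903, 0.168 and -0.0944. The letters may thus pair GFP- and control libraries, but no reference for chance correlations was computed, so this stays open. The labels do not state what a letter stands for.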

Results

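Gene expression was measured in 19 libraries of sorted mouse pancreatic cells by bulk MARS-seq, a method that counts the 3' ends of polyadenylated transcripts. The cells came from MIP-GFP mice, in which the insulin promoter drives green fluorescent protein (GFP), so that a cell that switches on insulin turns green. Exocrine cells, which are the enzyme-secreting and duct cells of the pancreas, were infected overnight with an adenovirus that carries the reprogramming cargo called M3 together with the red protein mCherry, or with a control adenovirus that carries mCherry alone. M3 is not spelled out in the sample labels; from general knowledge of the field it stands for the transcription factors Pdx1, Neurog3 and Mafa. On day 6 the cells were sorted into 4 populations. Control cells were mCherry+ cells of the control virus (n = 3). From the M3 infection came mCherry+ cells that had turned green (here called GFP+ cells, n = 4), mCherry+ cells that had stayed dark (GFP- cells, n = 4) and cells with neither color (double-negative cells, n = 4). GFP+ islet cells, sorted 24 h after isolation of the islets, served as the beta cell reference (n = 4).

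Libraries held 1444395 to 4738214 counts. The range was 1834900 to 3013071 in control cells, 3180634 to 4738214 in double-negative cells, 1505127 to 2264399 in GFP- cells, 1444395 to 3416039 in GFP+ cells and 3027680 to 3474283 in islet cells. Insulin transcripts (Ins1 and Ins2 together) took 53.6% ± 2.24 of the counts in islet cells (SD, n = 4). Their share was 0.197% ± 0.0377 in GFP+ cells, 0.0354% ± 0.00611 in GFP- cells, 0.00145% ± 0.000296 in double-negative cells and 0.00339% ± 0.00432 in control cells. The control value was carried by replicate F (0.008374%), and replicates C and E, at 0.0007633% and 0.001035%, were below the mean of double-negative cells. Replicate F held 34 counts of Ins1 and 140 of Ins2, a ratio of 0.243 near that of islet libraries (0.305 to 0.441). The ratios in C and E were 0.769 and 1.71, on few counts. Whether islet material reached replicate F was not tested. In a principal component analysis the first component took 63.3% of the variance and set islet cells apart, and the second took 20.6% and ordered the exocrine groups from control and double-negative through GFP- to GFP+ cells. Among GFP- libraries, replicate C stood apart on the third component, at -70.9 against -11.44 to 1.709 for the other GFP- libraries. Levels are given below as CPM (counts relative to the scaled library size), mean ± SD over libraries, and changes as log2 fold changes ± standard error. Gene p-values are from edgeR's quasi-likelihood test and list p-values from camera, all adjusted by the Benjamini-Hochberg method.

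The virus cargo came first, as a check of the labels. Pdx1 was at 92.23 ± 4.21 CPM in GFP- cells and 106.5 ± 53.5 in GFP+ cells against 1.46 ± 0.94 in control cells, and Neurog3 at 48.34 ± 16.2 and 35.98 ± 5.44 against 0.4217 ± 0.0935. Mafa reached 8.744 CPM in GFP- cells (7.254 to 10.07 over libraries) and 4.376 CPM in GFP+ cells (2.742 to 7.58) against 0.1076 CPM in control cells (0 to 0.3228). All 3 rose over control in both mCherry+ M3 populations (adjusted p from 9.91e-10 to 6.51e-05 over the 6 tests). Because control cells held 3 counts of Neurog3 and 1 of Mafa in all, the ratios of GFP- to control have wide counting intervals, 41.9 to 599 for Neurog3 and 11.1 to 2550 for Mafa. Double-negative cells had 4.553 ± 2.09 CPM of Pdx1, which missed the threshold against control (adjusted p = 0.134) but passed with DESeq2 (adjusted p = 0.0434). Between GFP+ and GFP- cells no factor passed the test, with log2 fold changes of 0.19 ± 0.28 for Pdx1 (adjusted p = 0.691), -0.44 ± 0.32 for Neurog3 (adjusted p = 0.387) and -1.08 ± 0.40 for Mafa (adjusted p = 0.06). Mafa did pass as lower in GFP+ cells without GFP+ replicate E (adjusted p = 0.0208), with limma voom (adjusted p = 0.0246) and with only these 8 libraries in the fit (adjusted p = 0.0478). The counts do not separate transcripts of the virus from those of the cells' own genes. They therefore do not measure how much virus cargo each population received. In the GRCm38 build, Pdx1 lies on chromosome 5 (147269959 to 147275848, plus strand), Neurog3 on chromosome 10 (62133090 to 62134763, plus strand), Mafa on chromosome 15 (75745490 to 75748228, minus strand), Ins1 on chromosome 19 (52264297 to 52265476, plus strand) and Ins2 on chromosome 7 (142678656 to 142743381, minus strand).

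**Figure D1:**
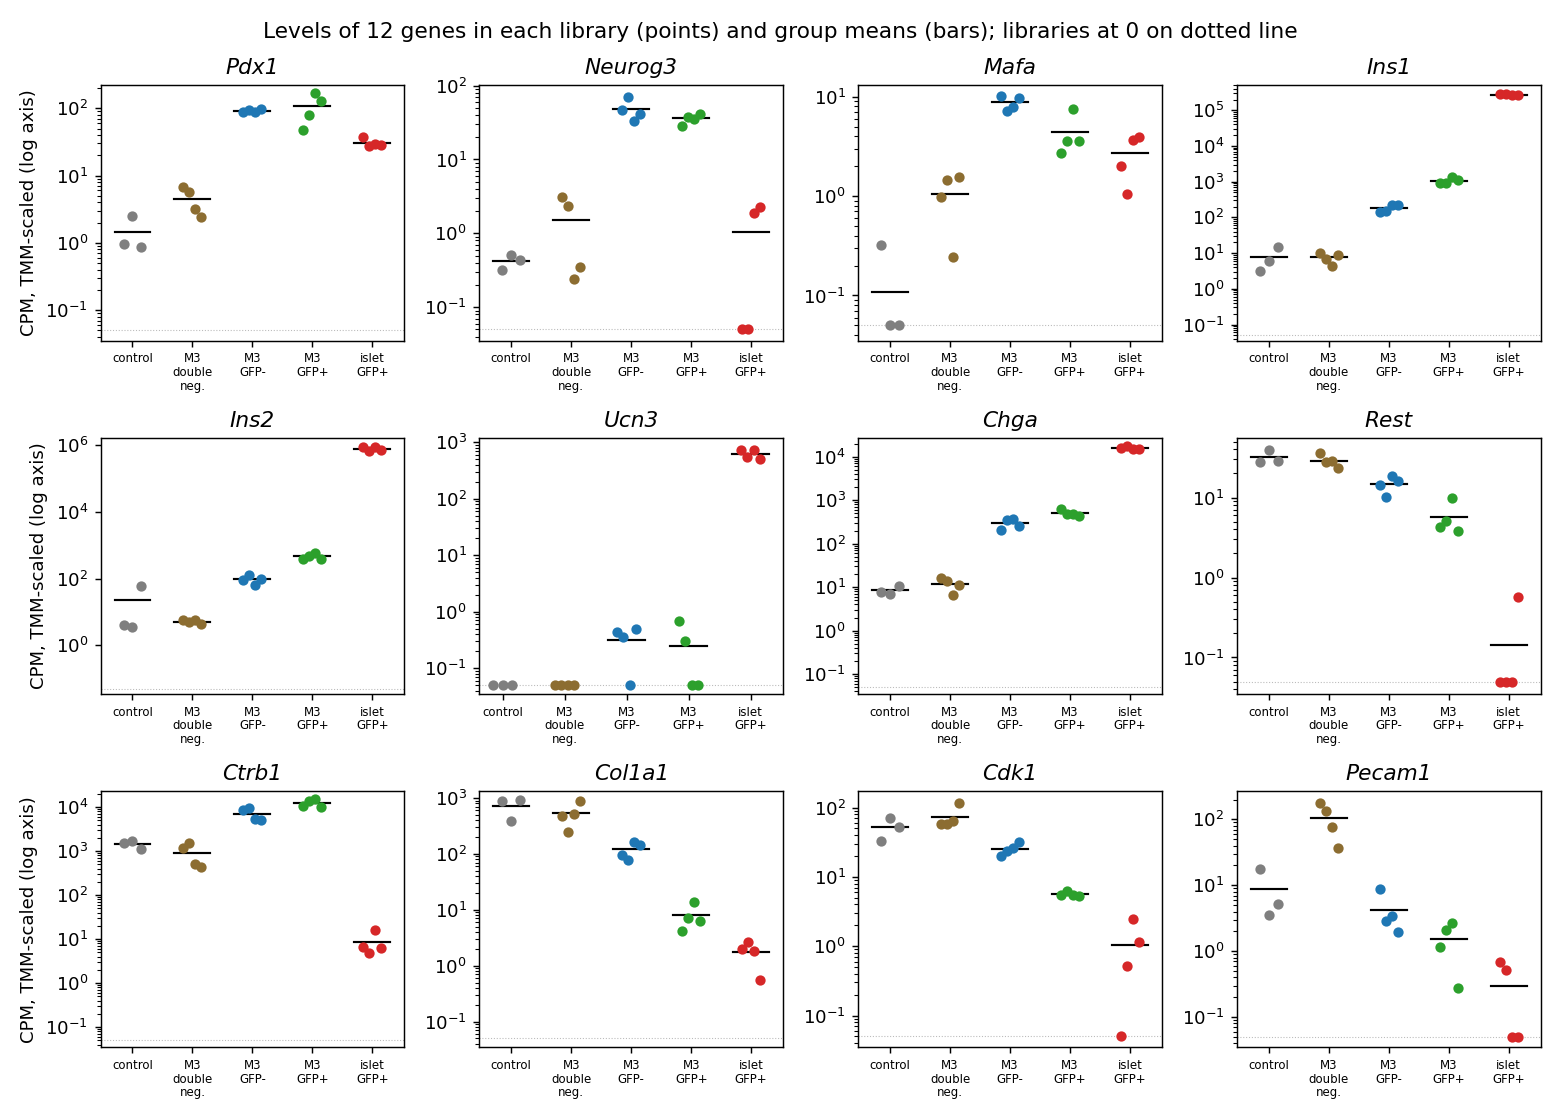
Level of 12 genes in each library, in CPM on log axes, one panel per gene; points are libraries (3 control, 4 in each other group), bars are group means and libraries with no count sit on the dotted line. Ins1 rises from 8.024 CPM in control cells through 185.7 in GFP- and 1073 in GFP+ cells to 274900 in islet cells, while Rest falls from 32.13 CPM in control cells to 5.762 in GFP+ cells.

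Cells that turned green were compared with M3 cells that stayed dark, which asks what accompanies activation of the insulin reporter. GFP+ cells had more insulin transcripts and more mRNA of REST targets, which include neuronal and secretory genes, and they had far less mRNA of matrix, duct and cell cycle genes. Ins1 was 5.783-fold higher (1073 ± 220 against 185.7 ± 45.4 CPM, adjusted p = 1.31e-07). Ins2 was 4.757-fold higher (457.8 ± 92.2 against 95.86 ± 26.7 CPM, adjusted p = 0.00345). The sort selects for activity of the insulin promoter, so higher insulin mRNA, here and within the beta cell list, is what the gate picks. The collagen gene Col1a1 was 16.5-fold lower (7.933 ± 4.3 against 121.1 ± 39.4 CPM, adjusted p = 6.37e-06) and Cdk1, the kinase that drives entry into mitosis, 4.484-fold lower (5.609 ± 0.478 against 25.43 ± 5.08 CPM, adjusted p = 1.83e-05). In all, 831 genes were higher and 1337 lower in GFP+ cells, of 12442 tested. The count of higher genes was 541 without GFP+ replicate D, 552 without GFP+ replicate F and 516 when only these 8 libraries were fitted.

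Among called genes with at least 50 CPM in the higher group and no overlap of libraries, the largest rises after insulin were those of Gem, a small GTPase that binds calcium channels (2.13 ± 0.48, adjusted p = 0.00494), Amelx, which codes for the enamel protein amelogenin (1.804 ± 0.413, adjusted p = 0.0054), Soga3 (1.76 ± 0.21), Mamdc2 (1.72 ± 0.22), Plk3 (1.68 ± 0.26) and Angptl7 (1.65 ± 0.41). Of the list of insulin and beta cell function, 10 of 30 measured members were higher and 2 lower, the same numbers when adjusted over the list alone (adjusted p = 0.000262). The count of higher members was 6 without GFP- replicate C, GFP- replicate F, GFP+ replicate E or GFP+ replicate F. Ero1lb, an oxidase of the endoplasmic reticulum that folds proinsulin, rose by 1.17 ± 0.19 (1072 ± 116 against 475 ± 49.2 CPM), and Slc6a17 by 1.54 ± 0.35. Against that direction, Nkx6-1, a transcription factor of mature beta cells, fell by 1.60 on the log2 scale (3.815 ± 1.59 against 10.97 ± 4.6 CPM, adjusted p = 0.000524). Hormones of other islet cells did not share the rise of insulin. Glucagon (Gcg) changed by 0.04 ± 0.60 (adjusted p = 0.979) and somatostatin (Sst) by -0.09 ± 0.56 (adjusted p = 0.938). Of 16 genes of other islet cells 1 was higher and 6 lower, also when adjusted over the list alone (adjusted p = 0.0227; adjusted p = 0.19 with an estimated correlation). Among them ghrelin (Ghrl) went down by 3.59 ± 0.55, Gc by 2.63 ± 0.34, Irx2 by 1.88 ± 0.31 and cholecystokinin (Cck) by 1.32 ± 0.30 on the log2 scale. That list no longer passed without GFP- replicate E (adjusted p = 0.0655) or GFP+ replicate C (adjusted p = 0.0736).

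Targets of REST, the repressor that keeps neuronal and endocrine genes off in other cells, rose. Genes of the regulated secretory pathway passed camera with the preset correlation and fry (adjusted p = 0.000678), but not camera with an estimated correlation. Of 42 measured REST targets 15 were higher and 0 lower (16 and 0 adjusted over the list alone; adjusted p = 3.46e-08). Among them were the vesicle gene Rab3c (1.32 ± 0.18), Crmp1 (1.63 ± 0.23) and Disp2 (1.00 ± 0.16). Of 34 granule and exocytosis genes 10 were higher and 0 lower (15 and 1 adjusted over the list alone; adjusted p = 1.57e-05), although with an estimated correlation the adjusted p = 0.0821. They include the prohormone processing enzyme Cpe (0.99 ± 0.21), Vgf (1.38 ± 0.29) and Tspan7 (0.71 ± 0.13); the granule list shares 11 genes with the REST list. Rest itself, picked after its values were seen, was at 14.75 ± 3.46 CPM in GFP- cells and 5.762 ± 2.71 in GFP+ cells, a log2 fold change of -1.44 ± 0.29 (adjusted p = 0.000855). Among endocrine transcription factors and Neurog3 targets 4 of 24 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.0117; adjusted p = 0.147 with an estimated correlation), and 7 were higher without GFP- replicate C. Neurod2 rose by 1.99 ± 0.27 and Cbfa2t2 by 0.85 ± 0.17, while Amotl2 went down by 1.15 ± 0.17 on the log2 scale. Genes of the unfolded protein and integrated stress responses were raised as well, 8 of 28 higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 9.09e-05), or 5 without GFP+ replicate F. Examples are Ppp1r15a (0.99 ± 0.20), Dnajb9 (0.98 ± 0.19) and Chac1 (0.80 ± 0.15). Of 20 p53 targets 7 were higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 0.00329), with Perp at 904.9 ± 118 against 457 ± 162 CPM and Bbc3, a cell death gene, at 82.02 ± 23.8 against 41.34 ± 11.2 CPM.

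The losses were larger than the gains. Of 17 fibroblast and stellate markers 16 were lower and 0 higher (17 and 0 adjusted over the list alone). That list had an adjusted p = 5.17e-24, or 0.00229 with an estimated correlation. Of 29 ductal and metaplasia genes 20 were lower and 0 higher (22 and 1 adjusted over the list alone; adjusted p = 6.65e-18). Bgn (-4.06 ± 0.36), Col3a1 (-3.78 ± 0.53), Tnc (-3.33 ± 0.21), Fbln2 (-3.19 ± 0.18), Fstl1 (-3.15 ± 0.30), Il11 (-3.36 ± 0.27) and Prg4 (-3.14 ± 0.30), which code for matrix proteins and secreted factors, had the largest falls with Col1a1 among called genes with at least 50 CPM in GFP- cells and no overlap of libraries. Clu, which codes for the secreted chaperone clusterin, was at 2746 ± 314 against 12020 ± 3240 CPM (adjusted p = 2.81e-08), Car2, the carbonic anhydrase of duct cells, at 5.69 ± 0.468 against 37.16 ± 5.2, and the adhesion receptor Cd44 at 43.77 ± 13.3 against 226.7 ± 52.3. Cell cycle genes were lower in 22 of 32 cases and higher in 0 (27 and 0 adjusted over the list alone; adjusted p = 3.77e-18). Ccna2 was at -3.12 ± 0.44, Rrm2 at -2.60 ± 0.37 and Birc5 at -2.52 ± 0.31. Of 20 genes repressed in mature beta cells 9 were lower and 0 higher (10 and 1 adjusted over the list alone; adjusted p = 7.54e-06), including Igfbp4 (-3.77 ± 0.55), Nfib (-2.58 ± 0.23) and lactate dehydrogenase Ldha (-0.95 ± 0.18). Markers of endothelial cells (1 of 14 lower, adjusted p = 0.113) and macrophages (2 of 7 lower, adjusted p = 0.207) did not pass as lists, but the endothelial list did without GFP- replicate F (adjusted p = 0.0226) or GFP+ replicate E (adjusted p = 0.0493). Fry called the macrophage list lower (adjusted p = 0.0413).

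Acinar genes, the genes of the enzyme-secreting cells, went both ways between the M3 populations. Of 30 acinar enzymes 3 were higher and 5 lower (4 and 6 adjusted over the list alone; adjusted p = 0.765); Gp2 rose by 1.09 ± 0.21 and Pnliprp2 by 1.07 ± 0.22, and Pnliprp1 went down by 1.35 ± 0.32 on the log2 scale. The lower count was 2 or 3 without GFP- replicate C or D or GFP+ replicate C, D or F. The acinar transcription factors Rbpjl (-3.20 ± 0.47), Ptf1a (-2.42 ± 0.43) and Nr5a2 (3.381 ± 1.53 against 14.47 ± 4.47 CPM, adjusted p = 0.000571) were lower in GFP+ cells, 3 of 9 list members (also 3 adjusted over the list alone), but the list did not pass (adjusted p = 0.197; 0.0484 without GFP- replicate C). Its median was 0.0770 and its mean -0.719, and fry called it lower (adjusted p = 0.00979). Among Notch pathway genes Hey1 rose (1.46 ± 0.20, adjusted p = 5.17e-06) and Hes1 fell (-1.66 ± 0.18, adjusted p = 1.66e-07), and the list did not pass (2 higher, 3 lower of 16; adjusted p = 0.964). The interferon (adjusted p = 0.263) and immediate early (adjusted p = 0.575) lists did not pass either.

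**Figure D2:**
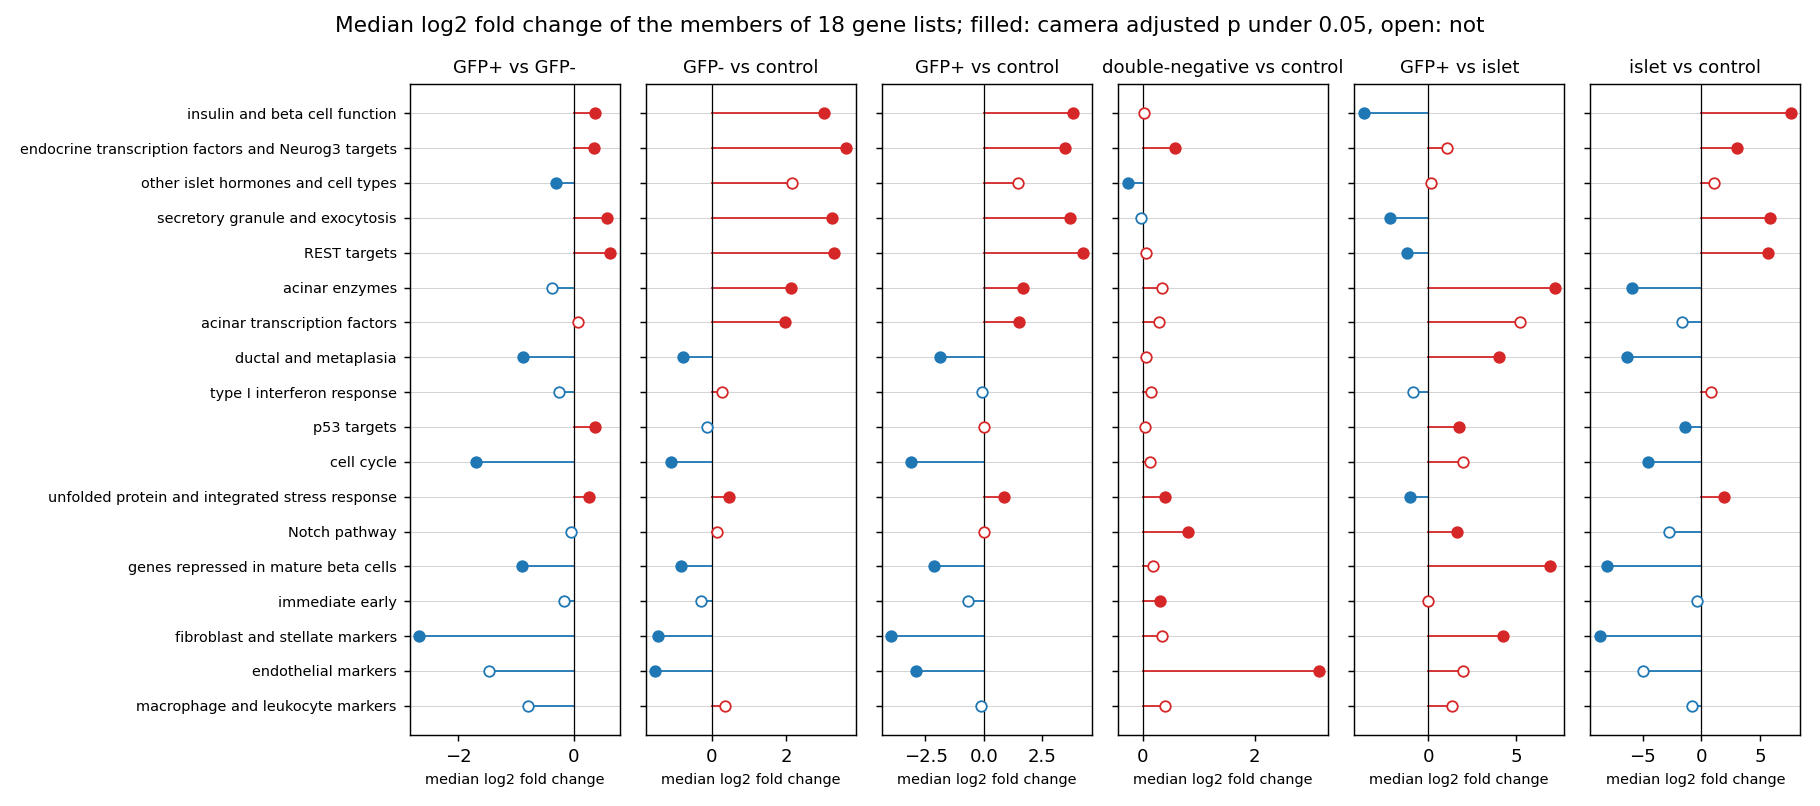
Median log2 fold change (horizontal axis) of 18 gene lists (vertical axis), one panel per comparison with its own axis range; red is higher and blue lower, and filled points passed camera at an adjusted p under 0.05. Cell cycle, ductal and fibroblast lists are lower in GFP+ than in GFP- cells; medians that include genes with no count in a group are fitted values, and setting such genes to a floor of 3 counts per group moved 33 of the medians, by up to 3.4 log2 units for acinar transcription factors in GFP+ against islet cells.

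GFP- cells were then compared with control cells, which asks what M3 did in infected cells whose reporter stayed off. These cells had higher levels of most endocrine transcription factors, granule genes and REST targets although they were not green. Their acinar enzyme mRNAs were also higher than in control cells, but that list lost its call with an estimated correlation (adjusted p = 0.174). The incretin hormone gene Gip rose 186.7-fold (1577 ± 335 against 8.24 ± 4.96 CPM, adjusted p = 5.09e-13), and the gut and islet hormone gene Pyy 27.99-fold (2553 ± 987 against 91.11 ± 24.5 CPM, adjusted p = 2.07e-07). Ins1 was already 23.63-fold higher (185.7 ± 45.4 against 8.024 ± 5.99 CPM, adjusted p = 2.01e-10), or 41.4-fold without control replicate F (adjusted p = 2.27e-10). Counts of changed genes were 2574 higher and 2082 lower, a balance that turned with RLE factors (2318 and 2403) and with DESeq2 (2321 and 2356).

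Other genes with large rises were Fam151a (7.46 ± 0.54), Prokr2 (6.71 ± 0.47) and the transcription factor gene Barhl1 (6.23 ± 0.40). Tyrosine hydroxylase (Th) and Cdk5r2 rested on 3 counts each in control cells, which puts the ratio at 47.8 to 683 for Th and 47.4 to 678 for Cdk5r2. Of 30 beta cell function genes 18 were higher and 0 lower (adjusted p = 2.86e-17). The proinsulin convertase gene Pcsk2 was at 479.7 ± 99.6 against 10.05 ± 5.04 CPM. Ins2 rose by 2.09 ± 0.58 (adjusted p = 0.00885) but missed the threshold when only the 7 libraries were fitted (adjusted p = 0.0808). Control replicate F held 60.68 CPM of Ins2 against 4.197 and 3.561 in the other control libraries, and without it the rise was 24.2-fold (adjusted p = 1.19e-09). Reads of Ins1 and Ins2, close paralogs, could have been split or dropped in counting. Sst rose by 4.14 ± 0.82 (adjusted p = 0.000919), and Gcg did not pass (-0.70 ± 0.64, adjusted p = 0.423). Endocrine transcription factors and Neurog3 targets were higher in 20 of 24 cases and lower in 1 (adjusted p = 5.25e-14). Rfx6 was at 5.61 ± 0.52, Tubb3 at 4.10 ± 0.33, Cbfa2t3 at 3.71 ± 0.28 and Nkx2-2 at 2.62 ± 0.28. Granule genes were higher in 27 of 34 cases and lower in 1 (adjusted p = 3.34e-26). Chromogranin A (Chga) was at 293.1 ± 78.8 against 8.569 ± 1.99 CPM and Syt13 at 224 ± 69.9 against 6.428 ± 0.828. Of the REST targets 31 of 42 were higher and 1 lower (32 and 1 adjusted over the list alone; adjusted p = 1.37e-22), and Rest was lower (-1.13 ± 0.27, adjusted p = 0.00146). Genes of other islet hormones and cell types moved both ways, 10 higher and 4 lower of 16, with Irx2 lower (-2.40 ± 0.26). That list missed the threshold (adjusted p = 0.0619) but passed with the replicate letter as a block (adjusted p = 0.0255) and without GFP- replicate C (adjusted p = 0.0163) or D (adjusted p = 0.0375). Fry called it higher (adjusted p = 0.000291).

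Acinar enzymes were higher in 24 of 30 cases and lower in 0 (25 and 0 adjusted over the list alone; adjusted p = 9.94e-09; adjusted p = 0.174 with an estimated correlation). Chymotrypsinogen (Ctrb1, outside the rule for named genes and picked after its values were seen) was at 7036 ± 2270 CPM in GFP- cells against 1447 ± 311 in control cells. Within the rule, Tff2 rose by 5.04 ± 0.50, Klk1 by 3.52 ± 0.39 and Gp2 by 3.02 ± 0.30. Acinar transcription factors were higher in 7 of 9 cases (8 adjusted over the list alone; adjusted p = 3.85e-05), among them Ptf1a (5.07 ± 0.67), Rbpjl (4.11 ± 0.62), Nr0b2 (5.75 ± 0.41) and Foxa2 (1.36 ± 0.24). Of the stress response list 12 of 28 were higher and 2 lower (14 and 2 adjusted over the list alone; adjusted p = 0.0111; adjusted p = 0.121 with an estimated correlation), with Sel1l at 2.65 ± 0.17 and Hsp90b1 at 1.73 ± 0.16.

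Duct genes were lower in 18 of 29 cases and higher in 4 (19 and 4 adjusted over the list alone; adjusted p = 3.07e-05). Krt19 was at 275.5 ± 33.5 against 1087 ± 92 CPM, and Krt23 and Car2 fell, whereas the progenitor marker Prom1 rose by 2.02 ± 0.21. The skin barrier genes Lce1h (-5.28 ± 0.32), Lce1g (-5.14 ± 0.30) and Lce1f (-4.35 ± 0.36), near copies of each other whose reads could be shared, and Bcl2l15 (-4.54 ± 0.26) had large falls. Gapdh, with 1.687 ± 0.654 against 181.3 ± 179 CPM, varied widely among control libraries (7.425 to 364.3 CPM) and ran from 0.6008 to 364.3 CPM over the 19 libraries. Its call was lost with limma voom (adjusted p = 0.396), without control replicate E (adjusted p = 0.0742) and without GFP- replicate C, D, E or F (adjusted p from 0.0514 to 0.0539). Cell cycle genes were lower in 23 of 32 cases and higher in 0 (25 and 0 adjusted over the list alone; adjusted p = 8.02e-09; adjusted p = 0.0532 with an estimated correlation), with Ccne1 at -2.49 ± 0.24 and Tyms at -1.67 ± 0.22. Of the 20 genes repressed in mature beta cells 11 were lower and 4 higher (12 and 4 adjusted over the list alone; adjusted p = 0.00785), including Hk1 (-1.69 ± 0.21) and Ldha (-1.52 ± 0.19); without control replicate E or F or GFP- replicate D 2 were higher. Fibroblast markers were lower in 13 of 17 cases (adjusted p = 7.89e-06; adjusted p = 0.129 with an estimated correlation). Endothelial markers were lower in 5 of 14 cases, 8 when adjusted over the list alone (adjusted p = 0.0149; adjusted p = 0.535 with an estimated correlation), and that list missed the threshold without control replicate C (2 lower, adjusted p = 0.0629). The lists of interferon response (adjusted p = 0.477), p53 targets (0.357), the Notch pathway (0.231), immediate early genes (0.161) and macrophage markers (0.861) did not pass camera, though Rsad2 (4.996 ± 0.41) and the lysosomal gene Cd68 (3.03 ± 0.38) rose. Fry called the Notch list higher (adjusted p = 6.64e-05) and the p53 (0.0371) and immediate early lists (0.0329) lower.

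GFP+ cells against control cells give the whole distance between green cells and cells of the control virus. Ins1 was 136.7-fold higher in GFP+ cells (1073 ± 220 against 8.024 ± 5.99 CPM, adjusted p = 8.29e-14) and Ins2 was 20.2-fold higher (adjusted p = 1.08e-05). Without control replicate F, which held the most insulin counts of the controls, the rises were 240-fold for Ins1 (adjusted p = 3.49e-13) and 115-fold for Ins2 (adjusted p = 8.25e-13). Angptl7 and the secreted peptide gene Prok2 had no count in any control library, which makes them at least 311-fold and 136-fold higher (floor of 3 counts over the group). Col1a1 was 99.53-fold lower (7.933 ± 4.3 against 727.6 ± 297 CPM, adjusted p = 2.15e-09). The test called 3377 genes higher and 3161 lower, and here too the balance turned with RLE factors (3066 and 3455) and with DESeq2 (3101 and 3546).

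Of the beta cell list 22 of 30 were higher and 2 lower (adjusted p = 1.06e-13), with Ero1lb at 6.34 ± 0.28 and Pcsk2 at 6.27 ± 0.29. The lists of endocrine transcription factors (19 of 24 higher, 1 lower; adjusted p = 1.39e-10), granule genes (28 of 34 higher, 2 lower; adjusted p = 9.01e-21) and REST targets (36 of 42 higher, 1 lower; adjusted p = 1.59e-20) also passed. Rest fell by 2.56 ± 0.29 on the log2 scale (adjusted p = 2.54e-08). Acinar enzymes were higher in 19 of 30 cases and lower in 1 (21 and 2 adjusted over the list alone; adjusted p = 6.34e-05; adjusted p = 0.381 with an estimated correlation). Acinar transcription factors were higher in 6 of 9 cases, with 1 lower (adjusted p = 0.0178; adjusted p = 0.116 with an estimated correlation). The stress response list had 18 of 28 higher and 2 lower (adjusted p = 0.000249). On the lower side, all 32 cell cycle genes (adjusted p = 1.81e-16) and all 17 fibroblast markers (adjusted p = 1.04e-13) fell, as did 23 of 29 duct genes, with 3 higher (adjusted p = 1.9e-11), and 14 of 20 genes repressed in mature beta cells, with 5 higher (adjusted p = 6.46e-05). Tnc (-5.59 ± 0.22) and Tm4sf1 (-4.76 ± 0.25) are examples. Endothelial markers were lower in 9 of 14 cases and higher in 1 (adjusted p = 0.0111; adjusted p = 0.535 with an estimated correlation).

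Double-negative cells came from the M3 infection but carried neither color, and their comparison with control cells differs in the sort gate as well as in the virus. The main difference was blood vessel mRNA. Each of the 14 measured endothelial markers was higher in double-negative cells (adjusted p = 2.47e-25, or 0.00727 with an estimated correlation). The adhesion gene Pecam1 was at 106.3 ± 61.7 against 8.732 ± 7.58 CPM and Cdh5, also an adhesion gene, at 96.3 ± 49.7 against 5.166 ± 5.12. The vessel growth factor gene Angpt2 was at 141.2 ± 73.1 against 6.46 ± 3.91. Beta cell function genes (0 higher, 1 lower of 30; adjusted p = 0.964) and granule genes (1 higher, 0 lower of 34; adjusted p = 0.986) did not move as lists. Ins1 was at 7.591 ± 2.53 against 8.024 ± 5.99 CPM (adjusted p = 0.989), a ratio that was 1.73 without control replicate F (adjusted p = 0.305) and 0.728 without control replicate C (adjusted p = 0.664). Ins2 had a log2 fold change of -2.13 that missed the threshold (adjusted p = 0.0571) and rested on control replicate F, with 60.68 CPM against 4.197 and 3.561 in the other controls. It passed with DESeq2 (adjusted p = 0.0179) and without control replicate C (adjusted p = 0.00744) or E (adjusted p = 0.0074), and without control replicate F its direction turned (0.378, adjusted p = 0.675). Here 437 genes were higher and 332 lower; without control replicate C the counts were 220 and 129, without control replicate E 276 were higher, and limma voom called 548 lower.

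Apln (3.33 ± 0.40), Robo4 (3.31 ± 0.42), Plvap (3.10 ± 0.33), Esam (2.97 ± 0.41) and Cd34 (3.67 ± 0.50) were among the genes that rose. Of 16 Notch pathway genes 5 were higher and 0 lower (8 and 0 adjusted over the list alone; adjusted p = 3.26e-05); Dll4, the Notch ligand of vessel tips, rose by 3.38 ± 0.61. Other lists passed on few called members, namely stress response genes (3 of 28 higher, 8 adjusted over the list alone; adjusted p = 0.000254), immediate early genes (4 of 18 higher, 5 adjusted over the list alone; adjusted p = 0.00119; adjusted p = 0.121 with an estimated correlation) and endocrine transcription factors (3 of 24 higher; adjusted p = 0.00278; adjusted p = 0.103 with an estimated correlation). Of that last list Ppp1r14a rose by 3.09 ± 0.435. These small counts hung on single libraries. Without control replicate C they were 3 for Notch, 0 for stress response and 0 for immediate early genes; without control replicate E, 2 for Notch, 1 for immediate early and 1 for endocrine genes; and leaving out control replicate F or any double-negative replicate also took some of them down to between 1 and 3. The list of other islet hormones and cell types went down, with the transcription factor genes Irx1 (-2.45 ± 0.40) and Irx2 (-2.71 ± 0.24) lower, no hormone gene called lower and 1 gene higher (1 and 3 adjusted over the list alone; adjusted p = 0.00785; adjusted p = 0.117 with an estimated correlation). Anxa10 (-3.35 ± 0.28), Bcl2l15 (-2.78 ± 0.23) and Bex1 (-2.04 ± 0.20) had large falls. With edgeR 0 of 42 REST targets were called, against 8 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom. Of 30 acinar enzymes 0 were called, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma voom. Acinar transcription factors and macrophage markers had 0 calls each with all 3 tools, and 1 each at an unadjusted p under 0.05. The acinar enzyme list (adjusted p = 0.559) passed without double-negative replicate E (adjusted p = 0.0367). The lists of fibroblast markers (adjusted p = 0.0917) and of genes repressed in beta cells (0.0985) passed without control replicate C (0.0079 and 0.0378), and the fibroblast list also without double-negative replicate D (0.0155).

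Sorted islet cells gave the distance that remained to beta cells. GFP+ cells carried 256.3-fold less Ins1 (1073 ± 220 against 274900 ± 13300 CPM, adjusted p = 5.33e-17) and 1681-fold less Ins2 (457.8 ± 92.2 against 769000 ± 104000 CPM, adjusted p = 1.24e-10). Several genes of mature beta cells were far lower in GFP+ than in islet cells, with Ucn3 and Slc30a8 near the floor. Examples are Ucn3, a maturity marker of beta cells (0.2465 ± 0.325 against 627.5 ± 120 CPM), the glucose phosphatase gene G6pc2 (2.56 ± 1.8 against 2976 ± 247), the zinc transporter gene Slc30a8 (0.6063 ± 0.158 against 477.5 ± 38.6) and Nkx6-1 (3.815 ± 1.59 against 622 ± 123). The test called 4315 genes higher and 3311 lower in GFP+ cells, with a median log2 fold change of 0.169 over all genes. CPM here are scaled by edgeR's factors, so that the insulin share of islet libraries does not push down their other genes, and their sum differs between libraries.

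Of 30 beta cell genes 26 were lower and 1 higher (adjusted p = 2.7e-31). Of 34 granule genes 25 were lower and 4 higher (adjusted p = 8.84e-14), including Scg2 (-9.03 ± 0.33), Chga (-4.99 ± 0.24) and Rab3a (-3.50 ± 0.17). REST targets divided, with 23 of 42 lower and 12 higher (adjusted p = 2.92e-05, lower as a list); Syt4 was at 3 counts in GFP+ cells, 295 to 4200 times lower than in islet cells, and Rab3c was 23.16-fold higher in GFP+ cells. Endocrine transcription factors went both ways, 13 higher and 8 lower of 24 (adjusted p = 0.402), with the early factor gene Sox4 higher (4.54 ± 0.23) and the islet factor gene Isl1 lower (-6.95 ± 0.25). Pdx1 was 3.424-fold higher and Neurog3 33.43-fold higher in GFP+ cells, and Mafa did not pass (0.61 ± 0.49, adjusted p = 0.283). Genes absent from islet libraries but present in GFP+ cells were Klk1 (at least 1020-fold), the neural genes Dpysl3 (at least 948-fold) and Nes (at least 852-fold), Igfbpl1 (at least 619-fold) and the trypsin gene Try4 (at least 378-fold, with close paralogs that could share reads). The neuropeptide gene Gal was at 8070 ± 1370 CPM against 2.287 ± 1.83. Acinar enzymes were higher in all 30 cases (adjusted p = 2.07e-15; adjusted p = 0.0751 with an estimated correlation). Duct genes were higher in 23 of 29 cases with 3 lower (adjusted p = 3.33e-10), and genes repressed in mature beta cells in 16 of 20 (adjusted p = 1.13e-10), among them Tgm2 (6.91 ± 0.26) and Ldha (7.67 ± 0.31). Of the p53 targets 15 of 20 were higher and 4 lower (adjusted p = 6.46e-05), with Cdkn1a at 1854 ± 315 against 112.5 ± 20.7 CPM. Stress response genes were lower in 19 of 28 cases and higher in 4 (adjusted p = 7.54e-06), such as Sdf2l1 (-3.81 ± 0.21) and Manf (-2.42 ± 0.19). Notch (10 higher, 2 lower of 16; adjusted p = 0.0279; adjusted p = 0.0532 with an estimated correlation) and fibroblast lists (10 higher of 17; adjusted p = 0.0217; adjusted p = 0.489 with an estimated correlation) were higher. Interferon genes (3 higher, 14 lower of 29) missed the threshold (adjusted p = 0.0784) but passed without islet replicate C (adjusted p = 0.0161) or D (adjusted p = 0.0396).

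Islet cells against control cells set the scale for the other comparisons. Ins1 was at 274900 ± 13300 against 8.024 ± 5.99 CPM (adjusted p = 4.48e-19). Its fold change hung on control replicate F, at 61100 without F against 25700 without C and 29700 without E. Ucn3, Slc30a8, Prlr and the serotonin synthesis gene Tph1 had no count in control cells, which makes them at least 1520-fold, 1170-fold, 1640-fold and 902-fold higher in islet cells. On the other side Wfdc2 and the prostaglandin synthase gene Ptgs2, with no count in islet cells, were at least 1240-fold and 1210-fold lower. The test called 3796 genes higher and 4570 lower, with a median log2 fold change of -0.125 over all genes.

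Of 30 beta cell genes 28 were higher and 0 lower (adjusted p = 1.17e-37). Of 34 granule genes 30 were higher and 2 lower (adjusted p = 2.41e-28) and of 42 REST targets 33 were higher and 2 lower (adjusted p = 3.82e-19). Rest was at 0.1415 ± 0.283 CPM in islet cells, 1 count in 4 libraries, against 32.13 ± 6.55 in control cells (adjusted p = 5.04e-12). Endocrine transcription factors (15 higher, 4 lower of 24; adjusted p = 0.000645; adjusted p = 0.0697 with an estimated correlation) and stress response genes (24 higher, 3 lower of 28; adjusted p = 2.24e-09) were higher. Acinar enzymes were lower in 28 of 30 cases (adjusted p = 2.67e-06; adjusted p = 0.296 with an estimated correlation), with Ctrb1 at 8.437 ± 5.16 against 1447 ± 311 CPM. Duct genes (23 of 29 lower, adjusted p = 5.48e-18), cell cycle genes (32 of 32, adjusted p = 3.33e-10), genes repressed in mature beta cells (20 of 20, adjusted p = 1.04e-13), p53 targets (14 lower, 4 higher of 20; adjusted p = 0.00353) and fibroblast markers (17 of 17, adjusted p = 2.08e-09; adjusted p = 0.0544 with an estimated correlation) were lower.

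A single number per library placed the M3 populations between control (0) and islet cells (1) by the mean log2 CPM of a list. For REST targets GFP+ libraries stood at 0.748 ± 0.015 and GFP- libraries at 0.599 ± 0.035. Granule genes gave 0.578 ± 0.022 and 0.486 ± 0.055, and beta cell genes 0.399 ± 0.017 and 0.324 ± 0.022. For endocrine transcription factors both means lay beyond the islet mean, at 1.39 ± 0.044 and 1.18 ± 0.15, although GFP- replicate C was at 0.9643. Camera, which sets a list against all other genes, did not call that list between GFP+ and islet cells (adjusted p = 0.402). Of its 24 members 13 were higher and 8 lower in GFP+ cells, and fry called the list higher (adjusted p = 0.000122). In each of these 4 lists every GFP+ library was above every GFP- library. This gives p = 0.0286 in an exact two-sided permutation test, the smallest that 70 splits allow, and an adjusted p = 0.0358 over 5 lists. The test takes the libraries as unpaired, although both gates come from the M3 infection. The beta cell list holds Ins1 and Ins2, which the sort on the insulin reporter selects for. With medians over members in place of means none of the 4 passed. Acinar enzymes stood on the far side of control from islets, at -0.424 ± 0.082 and -0.47 ± 0.1, and did not differ by this exact test (p = 0.486). GFP- replicate C lay low in its group; without it the GFP- means were 0.612 for REST targets, 0.511 for granule genes, 0.333 for beta cell genes and 1.25 for endocrine transcription factors.

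**Figure D3:**
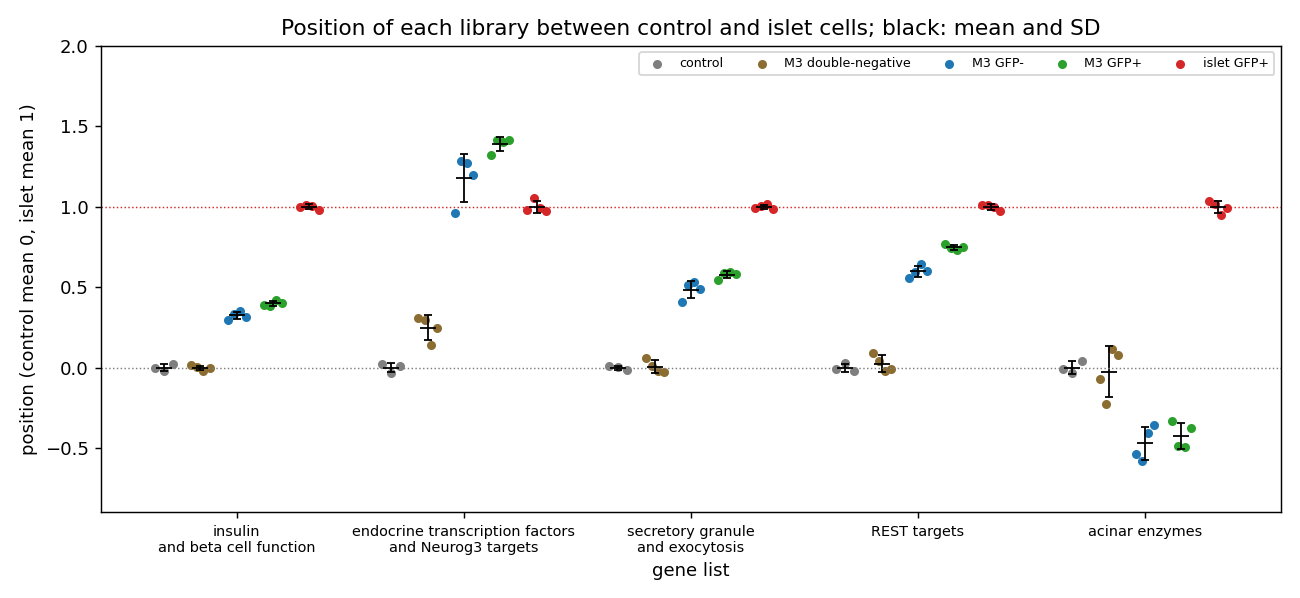
Position of each library (points) between the control mean (0) and the islet mean (1) for 5 gene lists, with black marks for group mean and SD; the vertical axis is the mean log2 CPM of the list on that scale. GFP+ libraries lie above GFP- libraries in the beta cell, endocrine, granule and REST lists, with means of 0.399, 1.39, 0.578 and 0.748. Means of double-negative libraries lie near 0 except in the endocrine list (0.249). For acinar enzymes single double-negative libraries run from -0.226 (D) to 0.118 (E).

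Whether genes that separate GFP+ from GFP- cells also separate islet from control cells was asked across genes, in contrasts that share no library. Over 12442 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.447 and a Spearman correlation of 0.341. Genes higher in both comparisons numbered 401 against 253.5 for independent lists, and genes lower in both 1082 against 491.1. In opposite directions 203 genes were higher in GFP+ and lower in islet cells (305.2 for independent lists) and 104 were lower in GFP+ and higher in islet cells (407.9). Col1a1, Clu and Cdk1 were lower in both GFP+ and islet cells, while Nkx6-1 and Amelx are genes in which the directions differed.

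**Figure D4:**
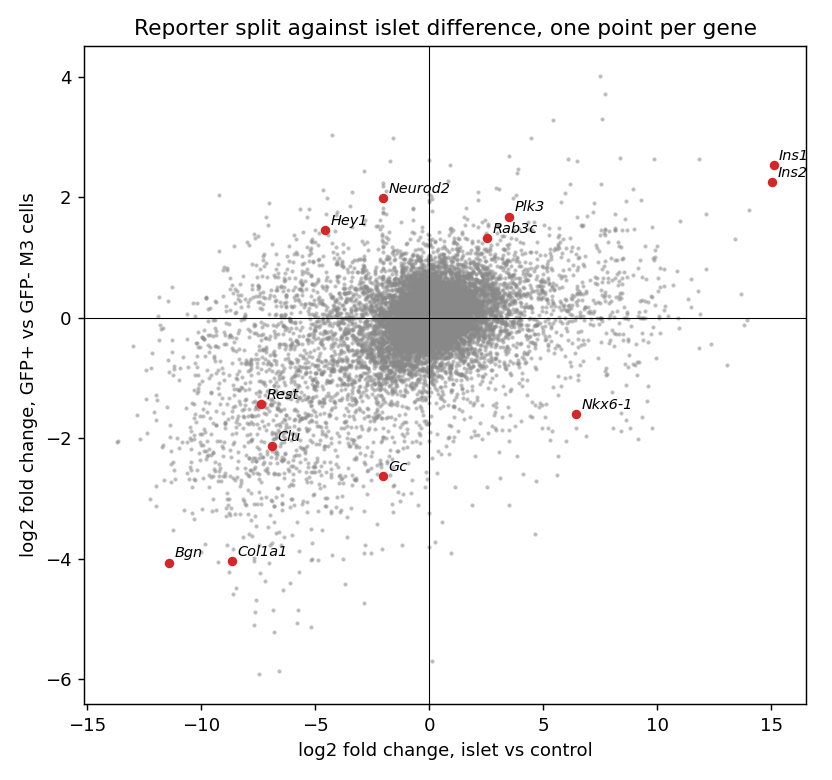
Log2 fold change of GFP+ against GFP- cells (vertical axis) and of islet against control cells (horizontal axis), one point per tested gene (12442 genes). The Pearson correlation is 0.447, and genes lower in both comparisons (1082) outnumber those lower in the first and higher in the second (104).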

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

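The tests in this part were chosen after the results were seen, except the test of GC content, whose prediction was written first. Dixon's ratio was applied to each list mean and named gene within groups of 4 libraries, and 25 of 449 tests (5.57%) passed, close to the 1 in 20 that chance gives.

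Among GFP+ libraries, replicate E was high for endothelial markers (0.924; 1.087 against 0.6217 log2 CPM), Cuzd1 (0.877; 6.497 against 2.717 CPM), Tagln (0.851; 60.1 against 36.97) and Col5a1 (0.832; 3.79 against 0.4516), and low for Cbfa2t2 (0.882; 64.97 against 78.83). Replicate C was low for endocrine transcription factors (0.898; 4.942 against 5.134 log2 CPM) and Cbfa2t3 (0.858; 65.11 against 93.39 CPM) and high for Chac1 (0.889; 171.4 against 128.8). Among GFP- libraries, replicate F was high for Nkx2-2 (0.848; 85.46 against 61.08) and Mcm7 (0.935; 86.44 against 68.02) and D for Pmaip1 (0.939; 30.83 against 21.22). Among double-negative libraries, F was high for Irx2 (0.84; 10.48 against 7.042) and D for Krt23 (0.972; 20.24 against 17.63).

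Among islet libraries, D was high for the Notch list (0.864; 1.942 against 1.645 log2 CPM) and Chga (0.839; 18020 against 15410 CPM), E for Clu (0.937; 223.7 against 167.6), and F low for Tph1 (0.842; 310.7 against 387) and C for Phlda3 (0.846; 0 against 0.5691). Ratios of 1 arose where a gene had counts in a single islet library, for Hey1, Fbn1 and Cxcl12 in D (0.5231 CPM each), Nr0b2 and Ankrd1 in C (0.6745 each) and Hk1 and Rest in F (0.566 each).

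Insulin in GFP+ cells could come from islet cells or islet RNA carried into the sort. The lowest Ins1 to Ins2 ratio of the GFP+ libraries was 1.95, against at most 0.441 in islet libraries, which argues against this source for Ins1. Cross-talk of sequencing indices from the islet libraries is likewise unlikely for Ins1, since the lowest GFP+ library had 61.1 times the Ins1 of the highest control or double-negative library (899.9 against 14.7 CPM). For Ins2 it stays open. Counts of G6pc2, Slc30a8, Ucn3 and Prlr in GFP+ libraries summed to 50 (95% Poisson interval 37.1 to 65.9), and 35.7 were needed to supply all Ins2; activation of Ins2 by M3 is also open, and islet RNA supplying all Ins2 would account for 15.4% of Ins1.

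Acinar enzyme mRNA in GFP- cells may be high because fewer non-epithelial cells were sorted, or because free acinar RNA was present. The 18 pan-epithelial markers had a median log2 fold change of -0.0193 (quartiles -0.405 to 0.399), and 6 of them are also in the ductal list. Acinar enzymes had a median of 2.12 (1.4 to 2.74). This argues against a gain of epithelial cells in general that is large enough to give the whole acinar rise. Fibroblast markers did fall (13 of 17 lower, median -1.44), so non-epithelial mRNA was not unchanged. Duct genes fell as well (18 of 29 lower), and a shift from duct to acinar cells was not tested. The rise in GFP- cells exceeded that in double-negative cells by a median of 1.7 log2 units (1.26 to 2.59), which argues against free RNA. An effect of M3 on acinar genes stays open, with the list at an adjusted p = 0.174 with an estimated correlation.

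GFP- replicate C stood apart from its group. Its deviations had a Spearman correlation of -0.178 with transcript length and of 0.199 with the GC content of the last 500 bases, while the largest in other libraries were 0.311 and 0.43. Low depth is also unlikely, as 2 other GFP- libraries had fewer counts. Its mean log2 CPM of endothelial markers was 2.2328, against 0.63817 to 1.1517 in the other GFP- libraries. Macrophage markers were at 3.6105 against 2.621 to 3.0281, while fibroblast markers, at 5.0428, were within the range of the others (4.8501 to 5.2336). No biological cause was tested.

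Whether any division of the libraries would give such counts was tested with all 35 splits of the libraries of each comparison, in fits of the 2 groups only. The real split was the only 1 of 35 with as many genes called in each of the 6 comparisons: GFP+ against GFP- cells (1421 genes, at most 0 in another split), GFP- against control (3323, 4), GFP+ against control (6321, 0), double-negative against control (614, 21), GFP+ against islet (7447, 0) and islet against control cells (7925, 0). For GFP- against control cells 8 splits part the 3 pairs, and among those the others called at most 0. With pairs kept the real split is thus 1 of 8, a share that cannot fall under 0.05, so that test cannot decide. In every comparison the other splits mix the groups, which adds the difference to the spread and holds their counts down.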

How the results depend on the processing

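Alternatives for the list tests and the correlation that leave out a library were chosen after the results were seen. Ins2 in double-negative cells, uncalled as reported, turned from lower to higher without control F, again uncalled. The balance of calls turned with RLE factors and DESeq2 for GFP- against control (2318 higher and 2403 lower; 2321 and 2356) and GFP+ against control (3066 and 3455; 3101 and 3546), and for GFP+ against control also without the filter (3242 and 3634), with only the 2 groups fitted (3152 and 3169) and without control E (2791 and 3119). With a 2-fold threshold 258 genes were higher and 865 lower for GFP+ against GFP-, 1681 and 1024 for GFP- against control, 284 and 142 for double-negative against control, and 2149 lower for GFP+ against islet cells. Fitting only the 2 groups gave 516 higher for GFP+ against GFP-, and limma voom 548 lower for double-negative against control cells. An estimated correlation left 7 lists for GFP- against control (12 as reported) and 3 for double-negative against control (6). It took 20 of 62 list calls in all. Fry, which does not set a list against the other genes, made 21 list calls that camera did not, and gave 18 for islet against control (11). Taking medians over members put GFP+ cells at 0.393, 1.16, 0.521 and 0.766 for beta cell, endocrine, granule and REST lists, and the exact test no longer passed (adjusted p = 0.114). Without the filter the correlations across genes were 0.352 and 0.298.

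Leaving out libraries gave 541 to 918 higher genes for GFP+ against GFP- (lowest without GFP+ D; 552 without GFP+ F). Double-negative against control cells ranged from 220 to 435 higher and from 129 to 351 lower (lowest without control C; 276 higher without control E). The Pearson correlation ranged from 0.425 to 0.461 and the Spearman correlation from 0.319 to 0.362. Without GFP- D, GFP- E or GFP+ E they left an interval that treats genes as independent. Genes are not independent, so that interval is too narrow and does not measure the spread between libraries. Of 5684 gene values 5612 kept their call.

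With the replicate letter as a block 892 genes were higher and 1360 lower for GFP+ against GFP- cells, 2499 and 2091 for GFP- against control, 3349 and 3155 for GFP+ against control, 459 and 354 for double-negative against control, 4322 and 3338 for GFP+ against islet and 3774 and 4540 for islet against control. Outside GFP- against control not every pair was above 0.1. For GFP+ against GFP- cells, both from the M3 infection, the correlations were 0.253 for C, 0.204 for D, 0.0692 for E and 0.0699 for F. There all but F matched their own letter best, so pairing by letter stays open for that comparison. The block brought the endothelial list of GFP+ against GFP- (adjusted p = 0.0483) and the fibroblast list of double-negative against control (adjusted p = 0.0255) under the threshold, and the other islet hormone list of GFP- against control (adjusted p = 0.0255), and it took Dnajc3 (adjusted p = 0.0543) and Calr (adjusted p = 0.0527) above it in double-negative cells; it changed no other list or named gene call.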

Other observations

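The readings below were chosen after the results were seen. On average over REST targets, infected M3 cells that were not green (GFP-) stood at 0.599 of the distance from control to islet cells, against 0.748 in green cells. That mean hides members on both sides, since in GFP+ cells 12 of 42 targets were above and 23 below islet cells. Rest mRNA fell in the same order, at 32.13 CPM in control, 14.75 in GFP-, 5.762 in GFP+ and 0.1415 in islet cells. Rest was picked after its values were seen, and the ordering does not show that it caused the rise of its targets. The position test was lost with medians over members (0.766 for GFP+ cells, adjusted p = 0.114), so the step between dark and green cells may rest on part of the list.

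Matrix, duct and cell cycle mRNA was lower in GFP+ than in GFP- cells, while Nkx6-1, a beta cell gene, was lower as well (3.815 against 10.97 CPM) and Ucn3 stayed near 0. Loss of fibroblast-like cells from the green gate could lower Col1a1 without a change inside any cell, and bulk counts do not tell these apart. Of 35 splits only the real one called as many genes, the smallest share that this test allows, and it takes the libraries as unpaired. Other splits mix the gates, which widens the spread within groups, so their counts do not measure chance calls.

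Double-negative cells held endothelial mRNA, and a gate on mCherry might let uninfected vessel cells through; with 220 to 435 genes higher on leaving out single libraries, the size of the difference is less certain than the 14 of 14 endothelial markers. Gapdh, often used as a reference gene, ranged from 0.6008 to 364.3 CPM over the 19 libraries, from 7.425 to 364.3 within the control group alone, so it is unsuited as a reference in these counts.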
